A study of Mus musculus with 35 samples.

How the data were processed

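RNA was sequenced from CD8 T cells of thymus and spleen that had been sorted by flow cytometry, in mice with a Cre transgene and a wild-type, heterozygous floxed or homozygous floxed Dot1l gene (WT, Het and KO). Per the labels' protocols, total RNA was extracted with Trizol, strand-specific libraries were made from mRNA with a TruSeq kit, and 65-base single reads were read on a HiSeq2500. Per the submitters' processing notes, the tools were TopHat2 2.1.0, TopHat and HTSeq 0.9.1 and the builds named were GRCm38 and mm10. The annotation release and the strand setting of the counting were not given in the sources used here, so overlapping genes on opposite strands may share counts. The values the authors deposited were raw counts, whole numbers of reads per Ensembl gene for each library in 1 table of 52636 genes. Of these, 19776 had at least 1 count, and no entry stood for unassigned reads. Gene symbols came from GENCODE M21 (GRCm38), which named 52403 of the identifiers, and the other 233 kept their identifier. Positions are from the same release.

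Each library was matched to its label by genotype, subset and replicate number in its name. The labels do not say that replicates came from separate animals, so p values measure the spread between these samples. No pair of libraries within a group looked like 1 library counted again: the lowest chi-square per gene over 51 pairs was 4.46, and the median 8.95. From Xist and Y-linked transcripts 24 libraries came from males and 11 from females, spread unevenly over the groups. Depth was 4809509 to 16879636 counts per library (median 10406516), which gives little precision for genes with a few counts. A limit of the table is that several abundant T cell transcripts had few counts for a reason not found here, so their counts cannot be read as their level, and lists of natural killer and myeloid genes kept only 2 tested members each and were not tested as lists.

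Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 9 groups (10296 genes), libraries scaled by TMM (factors 0.927 to 1.07), and a quasi-likelihood model with robust empirical Bayes estimates fitted over all 35 libraries with group means and 26 residual degrees of freedom. Two-sided p values of the quasi-likelihood F test were adjusted by Benjamini-Hochberg over all tested genes, and genes under 0.05 were called. Log2 fold changes are given ± standard error, taken as the size of the fold change over the square root of F. CPM values used the TMM scaling and are given ± SD. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, and again with an estimated correlation. The adjustment was over the lists with at least 3 tested members, leaving out the sex linked genes, which served as a check. Of the lists called in KO against WT libraries with the preset correlation, 4 of 8 in thymus, 2 of 9 in naive and 0 of 7 in memory cells held with the estimated one. The number of list members adjusted over the list alone is given beside the number over all genes tested. The memory signature took genes with an adjusted p under 0.05 and a log2 fold change over 1 between WT memory and naive libraries, and scores used log2 CPM with a prior count of 2. Score differences were tested by two-sided exact permutation of the libraries.

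The groups, the comparisons, the tests, the 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except a sex covariate and centring on the mean log level, which were chosen after seeing the data. Each KO against WT comparison names Dot1l, 12 key genes and the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap of library values, leaving out predicted models and immune receptor segments. Each list described names up to 4 members with the lowest adjusted p, apart from a few members named for what they encode. Other comparisons name Dot1l, up to 4 key genes and the 3 highest and 3 lowest by the same rule, and for the interaction terms the condition of no overlap cannot apply. The results of a few genes that these rules name are not reported here. B cell genes and the values of single naive KO libraries were chosen after their values were seen.

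Alternatives were RLE scaling, no filter on low counts, a stricter filter (CPM of at least 1 in 4 libraries), estimates that were not robust, only the libraries compared, DESeq2 1.42.0, the replicate number as a block, other signature thresholds, and each replicate left out in turn. Replicate numbers recur across groups. Correlations of the deviations from the group means between equally numbered libraries were over 0.1 for every pair only for KO against WT naive (0.130 to 0.258), KO against Het naive and memory against naive WT libraries, a pairing read from the data and not from the labels. The test was run on simulated data for KO against WT naive libraries with 9994 genes. It recovered 40 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 63 of 66 changed 4-fold with 8 false calls, and 1 raised list of 24 was called. Genes and libraries were drawn independently. The simulation therefore cannot show false calls that come from correlation between genes or between equally numbered libraries. Splits of the libraries into other groups of the same sizes were counted for each comparison.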

Results

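Gene expression was measured by RNA sequencing in CD8 T cells sorted from C57BL/6 mice that carried a Cre transgene and 0, 1 or 2 floxed copies of Dot1l, the gene of the histone methyltransferase that methylates lysine 79 of histone H3. The genotypes are called WT, Het and KO here. Each genotype was sampled in 3 subsets, namely CD8 single positive cells of the thymus, naive cells of the spleen (CD44 negative, CD62L positive) and memory cells of the spleen (CD44 positive, CD62L positive). The 35 libraries fell into 9 groups of 4, except WT thymus with 3. Total counts ranged from 4809509 to 16879636 per library, with a median of 10406516, and 10296 genes had enough counts to be tested. Counts were uneven over transcripts that CD8 T cells hold in abundance. Actb took 7.20% to 10.8% of the counts of a library, and Lck had a mean of 10191 counts per library, but Cd8a had a mean of 92.0, B2m 53.3, Cd3d 21.3 and Gapdh 31.3. Ifng, 1 of the 12 key genes, had at most 1 count in any library and was not tested.

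Dot1l (chromosome 10, 80755206 to 80795461, GRCm38) was not lower in the libraries labelled KO. In thymus its level was 67.0 ± 5.20 CPM in WT (SD, n = 3), 69.2 ± 4.41 in Het (n = 4) and 77.3 ± 1.68 in KO libraries (n = 4). In naive cells it was 49.5 ± 2.08, 52.2 ± 2.79 and 55.7 ± 1.26 CPM. In memory cells it was 45.4 ± 5.81, 47.6 ± 4.72 and 45.8 ± 1.88 CPM (n = 4 each). The adjusted p of KO against WT was 0.0891 in thymus, 0.163 in naive and 0.961 in memory cells (edgeR). DESeq2 called Dot1l higher in thymus KO libraries (adjusted p = 0.0428). The labels do not say which part of the gene is floxed, so a count over the whole gene cannot check the deletion. Every direction below is that of the libraries labelled KO.

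**Figure D1:**
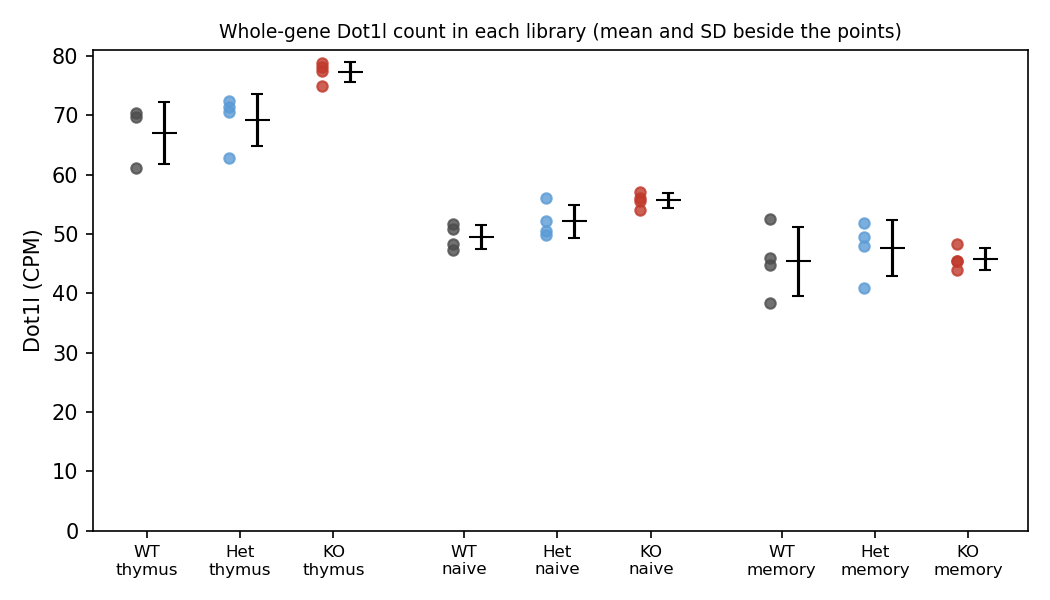
Dot1l CPM in each library by genotype and subset, with the mean and SD of each group. KO libraries lay at 77.3 CPM in thymus, 55.7 in naive and 45.8 in memory cells on average, not below the WT libraries.

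In the thymus, 8 of 11 tested effector genes and 9 of 20 memory genes were higher in KO than in WT libraries. The effector list held 22 genes. Those not tested in any subset included the granzyme genes Gzma and Gzmb, with at most 2 and 1 counts in any library. With an estimated correlation the effector list held its call (adjusted p = 0.00811) and the memory list lost it (adjusted p = 0.134). Eomes and Tbx21, the T-box transcription factors of effector and memory cells, stood at 45.4 ± 7.12 against 9.61 ± 2.59 CPM (log2 fold change 2.29 ± 0.21 SE) and at 16.7 ± 2.15 against 2.48 ± 0.88 CPM (2.85 ± 0.40). Lef1, a transcription factor of naive T cells, fell from 1097 ± 64.3 to 714 ± 30.5 CPM (log2 fold change -0.62 ± 0.08, n = 4 KO and 3 WT libraries). Highest and lowest fold changes are named here and below among called genes with a mean log2 CPM of at least 1 and no overlap of library values. Within these limits the highest in thymus included Zbtb16, which encodes the innate-like T cell factor PLZF (4.18 ± 0.56), S100a6 (3.90 ± 0.44), Plek (3.62 ± 1.01), Agap1 (3.50 ± 0.62), Lgals3 (3.36 ± 0.51) and Dapk2 (3.13 ± 0.57). Without WT replicate 1 Zbtb16 was at 5.24. The lowest within them were Tuba3a (-2.05 ± 0.24), Rgmb (-1.69 ± 0.35), Izumo1r (-1.65 ± 0.24), Tmie (-1.37 ± 0.22), Igf2bp3 (-1.32 ± 0.33) and Sox4 (-1.28 ± 0.20). Of the other key genes, the integrin gene Itga4 rose by 1.12 ± 0.17 and Il2rb, an interleukin receptor chain, by 0.62 ± 0.21, and the homing receptor gene Ccr7 fell by 0.35 ± 0.10. Cxcr3 was called higher too (log2 fold change 3.45, and 5.16 without WT replicate 2). It was at 0.45 ± 0.31 CPM in KO libraries with 1 count over the WT libraries together, so the size of its change is uncertain. Cd44 (0.82 ± 0.32, adjusted p = 0.0737), Tcf7 (-0.09 ± 0.07, adjusted p = 0.416) and Ezh2 (0.23 ± 0.12, adjusted p = 0.202) did not pass the test in edgeR with all libraries in the fit. Cd44 passed with only the libraries compared (adjusted p = 0.0142), with the replicate block (adjusted p = 0.00171), with the sex covariate (adjusted p = 0.0446), without KO replicate 1 (adjusted p = 0.0486) and in DESeq2 (adjusted p = 0.0411). Equally numbered KO and WT thymus libraries did not deviate together (mean correlation -0.0281), so the block has no support in the data there. Ezh2 passed with only the libraries compared (adjusted p = 0.0459).

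Of the 11 tested effector genes 8 rose and none fell, both over all genes tested and adjusted over the list alone, with Anxa2 (2.02 ± 0.21), S100a6 and S100a4 (3.87 ± 0.54) among them (list adjusted p = 5.2e-11). Of the 20 tested memory genes 9 rose, 11 adjusted over the list alone, with Bhlhe40 at 2.42 ± 0.23 (list adjusted p = 4.5e-07, lost as given above). Of 22 genes of naive cells and quiescence 10 fell and 1 (S1pr1, an egress receptor) rose, in the same numbers adjusted over the list alone. They included Satb1 (-0.90 ± 0.06), Btg1 (-0.93 ± 0.10) and Foxp1 (-0.40 ± 0.06), and the list passed both ways (adjusted p = 4.5e-07, and adjusted p = 0.0231 with an estimated correlation). Of 29 T cell receptor signalling genes 9 fell, and adjusted over the list alone 13 fell and 1 (Nfatc2, 0.27 ± 0.10) rose. Among those that fell were the negative regulator Cd5 (-0.97 ± 0.14) and the zeta chain gene Cd247 (-0.61 ± 0.09). Their list had an adjusted p of 1.8e-07, and adjusted p = 0.0554 with an estimated correlation. Proliferation genes rose in number in thymus, 18 of 24 and 21 adjusted over the list alone. Among them were the replication licensing genes Mcm2 (0.72 ± 0.07), Mcm6 (0.70 ± 0.08) and Mcm4 (0.62 ± 0.08), below the list median of 0.84. The list had an adjusted p of 3.2e-12, and adjusted p = 0.0281 with an estimated correlation.

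Of the 11 immature single positive genes 5 fell and 2 rose (6 and 3 adjusted over the list alone), with Sox4 and Tox (-0.50 ± 0.09) lower and Rag1 (1.21 ± 0.40) higher (list adjusted p = 0.00013, and adjusted p = 0.0138 with an estimated correlation). Of 17 activation and immediate early genes 6 fell, also adjusted over the list alone, with Nfkbia at -0.51 ± 0.09 and Nr4a1 at -0.65 ± 0.17 (list adjusted p = 0.00485, but adjusted p = 0.332 with an estimated correlation). Of 10 heat shock and sorting stress genes 6 rose, also adjusted over the list alone, with Hspd1 at 0.76 ± 0.10 and Hsp90aa1 at 0.93 ± 0.16 (list adjusted p = 0.00159, but adjusted p = 0.305 with an estimated correlation). These genes can respond to handling, so they are given as a measured difference between the thymus groups. Over all genes 1222 were higher and 697 lower, 1919 in all. With the libraries centred on the mean log level, which moved the median gene by -0.10 on the log2 scale, the split turned to 886 higher and 1327 lower. The lowest count without 1 library was 1409, and Il2rb lost its call in 6 of the 7 fits without a thymus library (highest adjusted p = 0.25) and with mean log centring (adjusted p = 0.072). Plek (adjusted p = 0.0668) and Igf2bp3 (adjusted p = 0.0594) lost theirs without WT replicate 2, and Ccr7 without KO replicate 3 (adjusted p = 0.0601) or WT replicate 3 (adjusted p = 0.0664).

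In naive cells of the spleen, 10 of 11 effector genes and 12 of 20 memory genes were higher and 9 of 22 naive and quiescence genes lower in KO than in WT libraries. With an estimated correlation the effector list held its call (adjusted p = 0.00137), and the memory list (adjusted p = 0.0617) and the naive list (adjusted p = 0.231) lost theirs. Bhlhe40, a transcription factor of resident and effector T cells, was at 15.7 ± 7.23 CPM against 0.53 ± 0.42 (log2 fold change 4.72 ± 0.31, n = 4 each), Tbx21 at 75.0 ± 34.9 against 15.7 ± 5.26 (2.22 ± 0.26) and Eomes at 139 ± 30.4 against 57.1 ± 9.18 (1.28 ± 0.17). Lef1 fell to 755 ± 61.5 from 1241 ± 67.6 CPM (-0.72 ± 0.07) and Ccr7 to 90.5 ± 7.58 from 135 ± 12.1 (-0.58 ± 0.09), while Tcf7 rose by 0.31 ± 0.06. Within the limits given above the highest fold changes also included Soat2, a cholesterol acyltransferase (5.10 ± 0.26), the semaphorin coreceptor gene Nrp1 (4.89 ± 0.23), Ncald (4.80 ± 0.34), Glis3 (4.71 ± 0.54) and Kalrn (4.71 ± 0.43, and 5.65 without WT replicate 3). The lowest within them were Slc35g1 (-2.85 ± 0.23), Pcsk1 (-2.29 ± 0.33), Igfbp4 (-2.21 ± 0.22), the cytokinesis gene Racgap1 (-1.92 ± 0.12), Rgmb (-1.76 ± 0.34) and Trim59 (-1.70 ± 0.18). Of the other key genes Cd44 (1.61 ± 0.30), Il2rb (1.25 ± 0.20), Cxcr3 (1.06 ± 0.29) and Itga4 (0.88 ± 0.15) rose and Ezh2, the catalytic subunit of the histone methyltransferase PRC2, fell by 0.54 ± 0.12.

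Of the 11 tested effector genes 10 rose, also adjusted over the list alone, with Anxa2 (2.71 ± 0.21), S100a6 (3.80 ± 0.40) and the chemokine gene Ccl5 (3.81 ± 0.49) among them (list adjusted p = 4.6e-15). Of 20 memory genes 12 rose, 13 adjusted over the list alone, with Itgb1 at 1.87 ± 0.22 (list adjusted p = 5.3e-11, lost as given above). Of 22 naive and quiescence genes 9 fell and 2 rose, also adjusted over the list alone, with Satb1 at -0.34 ± 0.05 and Tob1 at 0.83 ± 0.12 (list adjusted p = 0.00497, lost as given above). Of 29 T cell receptor signalling genes 7 fell, 8 adjusted over the list alone, among them Cd247 (-0.68 ± 0.09), Cd6 (-0.75 ± 0.10) and Cd5 (-0.99 ± 0.15). This list had an adjusted p of 0.00464 and adjusted p = 0.325 with an estimated correlation. Of 21 interferon stimulated genes 8 rose and 1 fell, 11 and 1 adjusted over the list alone. They included the antiviral genes Rsad2 (2.14 ± 0.33), Mx1 (1.16 ± 0.24) and Oas3 (1.12 ± 0.24). The adjusted p of the list was 0.0012 and adjusted p = 0.304 with an estimated correlation.

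Among 11 inhibitory receptor and exhaustion genes 3 rose and 1 fell, 6 and 1 adjusted over the list alone, and the list passed both ways (adjusted p = 0.00323, and adjusted p = 0.0357 with an estimated correlation). Those that rose were Ikzf2, the transcription factor Helios (2.28 ± 0.23), the receptor gene Cd160 (1.45 ± 0.22) and the orphan nuclear receptor gene Nr4a1 (1.18 ± 0.20). Of 17 integrin and adhesion genes 6 rose and 1 fell (9 and 2 adjusted over the list alone), with Itgb3 at 1.64 ± 0.15 (list adjusted p = 0.00736, but adjusted p = 0.0956 with an estimated correlation). Of 14 cholesterol synthesis genes 3 fell, also adjusted over the list alone, with the regulator Srebf2 at -0.62 ± 0.08 (list adjusted p = 0.0147, but adjusted p = 0.325 with an estimated correlation). Of 7 genes of CD4 T cells 3 rose and 1 fell, 4 and 1 adjusted over the list alone, with Gata3 at 0.63 ± 0.09 and Cd5 the one that fell (list adjusted p = 0.0391, but adjusted p = 0.0956 with an estimated correlation). Ikzf2 was among those that rose in this list too, and Cd4 itself was not tested. Over all genes 1147 were higher and 732 lower. Centring on the mean log level, which moved the median gene by -0.12, gave 876 higher and 1663 lower.

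The naive KO libraries were not alike. Replicate 3 had 17.95 CPM of Cd44 against 5.49 to 6.30 in the others, and 26.4 CPM of Bhlhe40 against 10.95 to 12.84. Its memory signature score, defined below, was 0.57 against -0.50 to -0.27. By Xist and Y-linked transcripts it came from a female and the others from males. Replicate 4 had the highest level of all 12 tested B cell genes among the naive KO libraries, with H2-Aa at 73.2 CPM against 1.42 to 12.4 in the others and Cd74 at 38.0 against 2.28 to 4.52, although none of the 12 was called higher (list adjusted p = 0.87). The 1879 genes called in naive cells became 1573 without replicate 3 and 1674 without replicate 4. Cd44 lost its call with only the compared libraries in the fit (adjusted p = 0.081) and Tcf7 with centring on the mean log level (adjusted p = 0.0507).

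In memory cells of the spleen, 9 of 11 effector genes were higher and 8 of 22 naive and 11 of 29 receptor signalling genes lower in KO than in WT libraries. With an estimated correlation all 3 lists lost their call (adjusted p = 0.0749, 0.181 and 0.265). Within the limits given above Cdc42bpa had the highest fold change, with 25.1 ± 1.89 against 0.49 ± 0.45 CPM (log2 fold change 5.61 ± 0.33, n = 4 each). It was followed with all libraries by Kalrn (4.87 ± 0.38), the glutathione transferase gene Gstm1 (4.53 ± 0.47), Nrp1 (4.43 ± 0.19), the sulfatase gene Sulf2 (4.33 ± 0.58) and Atp8a2 (4.31 ± 0.14). This order rested on single WT libraries: without WT replicate 1 Gstm1 was at 6.83, Kalrn at 5.79 and Cdc42bpa at 5.40, and without WT replicate 4 Cdc42bpa was at 6.45. The lowest within them were Plce1, a phospholipase C (-4.71 ± 0.32), Tuba3a (-2.77 ± 0.30), Trim59 (-2.49 ± 0.18), Igfbp4 (-2.37 ± 0.32), Dlg5 (-2.36 ± 0.37) and the phosphatase gene Inpp4b, which fell from 320 ± 18.7 to 64.4 ± 6.53 CPM (-2.31 ± 0.08). Eomes rose to 315 ± 42.7 from 181 ± 12.5 CPM (0.80 ± 0.16), Itga4 by 0.78 ± 0.16 and Il2rb by 0.50 ± 0.16, and Lef1 (-0.62 ± 0.07), Ccr7 (-0.57 ± 0.09) and Ezh2 (-0.38 ± 0.12) fell. Cd44 (-0.01 ± 0.21, adjusted p = 0.986), Tbx21 (0.37 ± 0.22, adjusted p = 0.284), Tcf7 (0.14 ± 0.06, adjusted p = 0.125) and Cxcr3 (-0.26 ± 0.23, adjusted p = 0.483) did not pass the test.

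Of the 11 tested effector genes 9 rose, also adjusted over the list alone, among them Anxa2 (2.18 ± 0.19), Zeb2 (3.37 ± 0.37) and Prdm1, the gene of Blimp-1 (1.85 ± 0.24). Their list had an adjusted p of 1.2e-06, lost as given above. Of 20 memory genes 9 rose, also adjusted over the list alone, with Bhlhe40 at 3.78 ± 0.21 and Id2 at 2.28 ± 0.17 (list adjusted p = 4.8e-05, but adjusted p = 0.265 with an estimated correlation). Of 22 naive and quiescence genes 8 fell and 1 rose, 11 and 1 adjusted over the list alone, with Actn1 at -1.03 ± 0.08 and Satb1 at -0.42 ± 0.05 (list adjusted p = 0.00031, lost as given above). Of 29 T cell receptor signalling genes 11 fell, 13 adjusted over the list alone. The negative regulators Cd6 (-1.50 ± 0.10) and Cd5 (-1.81 ± 0.14) fell most clearly. The list had an adjusted p of 0.00021, lost as given above. Of 7 tested HOXA genes and cofactors 5 rose, 6 adjusted over the list alone. They were Pbx3 (1.48 ± 0.29), Meis1 (2.99 ± 0.65), Hoxa3 (2.41 ± 0.80), Hoxa2 (2.43 ± 0.81) and Hoxa4 (2.12 ± 0.76). The adjusted p of this list was 0.0177 and adjusted p = 0.145 with an estimated correlation.

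Proliferation genes were higher in 9 of 24 cases in memory cells, 10 adjusted over the list alone, with Mcm2 at 0.78 ± 0.07 and Mcm5 at 0.90 ± 0.12 (list adjusted p = 0.00021, but adjusted p = 0.297 with an estimated correlation). Of 21 interferon stimulated genes 7 rose, also adjusted over the list alone, with Gbp3 at 0.67 ± 0.12, Irf9 at 0.41 ± 0.08 and Rsad2 at 1.31 ± 0.29 (list adjusted p = 0.0177, but adjusted p = 0.497 with an estimated correlation). Over all genes 1323 were higher and 960 lower, 2283 in all. Centring on the mean log level, which moved the median gene by -0.12, gave 1013 higher and 1865 lower. Ezh2 lost its call without KO replicate 1 (adjusted p = 0.0551) or WT replicate 4 (adjusted p = 0.0558), and Il2rb with mean log centring (adjusted p = 0.0609) and without KO replicate 4 (adjusted p = 0.0502), WT replicate 1 (adjusted p = 0.056) or WT replicate 2 (adjusted p = 0.0821).

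**Figure D2:**
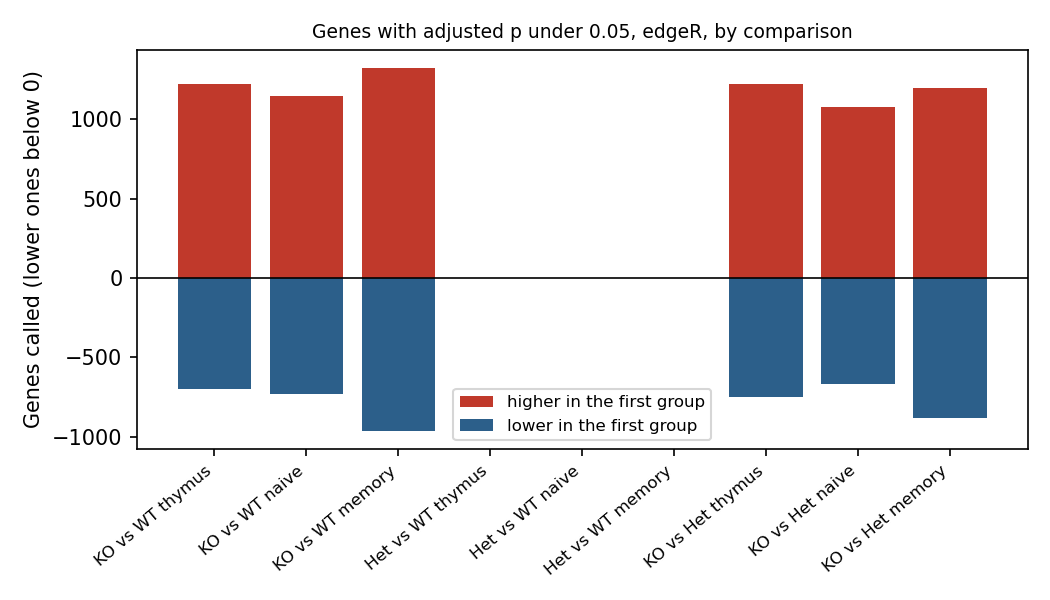
Number of genes called higher and lower (adjusted p under 0.05, edgeR) in each comparison. The comparisons of KO with WT or Het libraries called 1745 to 2283 genes, and those of Het with WT libraries at most 1.

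Genes called in 1 subset were often called in another in the same direction. Thymus and naive cells shared 525 higher genes, where independent lists of those lengths would share 136, and 263 lower genes against 49.6. Thymus and memory cells shared 564 higher genes against 157 and 290 lower genes against 65.0, and naive and memory cells 815 against 147 and 493 against 68.3. In all 3 subsets 421 genes were higher and 203 lower in KO libraries, among them Eomes and Lef1. The pairs of comparisons shared no library. However, equally numbered naive and memory libraries deviated together in WT (correlations 0.126 to 0.243) and KO (mean 0.137), which the numbers for independent lists leave out. They also leave out that calls went with expression level. In Het libraries lower genes had a median log2 CPM of 6.01 to 6.25 over the subsets, against 3.53 to 3.63 for genes not called.

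**Figure D3:**
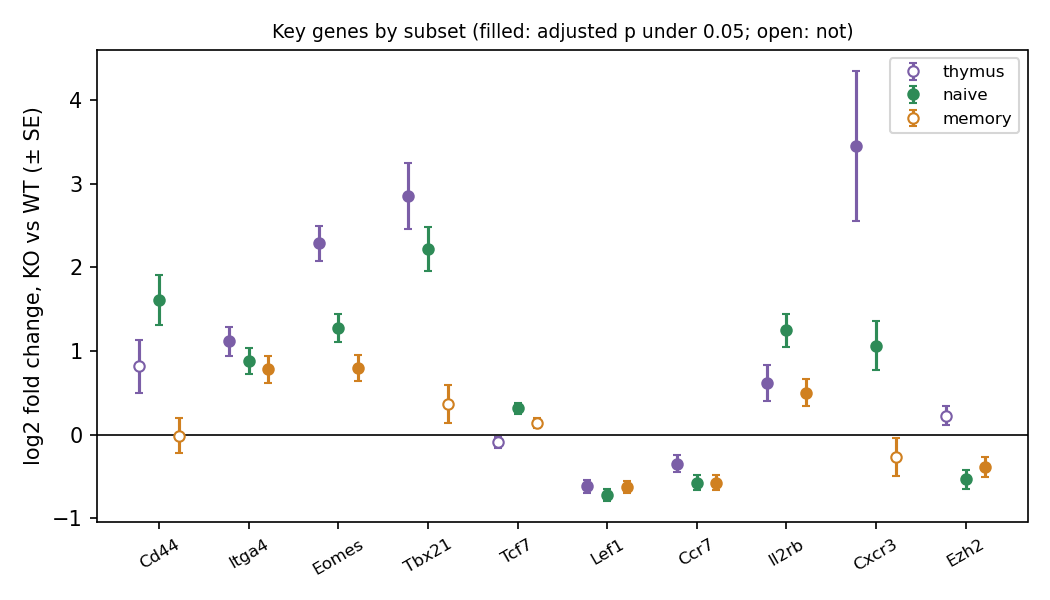
Log2 fold changes of the key genes, KO against WT libraries, in each subset, with the standard error of each. Eomes was higher (2.29, 1.28 and 0.80) and Lef1 lower (-0.62, -0.72 and -0.62) in thymus, naive and memory cells.

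The KO effect was set against itself between subsets by an interaction term. From thymus to naive cells it differed for 653 genes (310 higher in the naive effect, 343 lower). It was lower for Ezh2 (-0.76 ± 0.17), Eomes (-1.01 ± 0.27), Racgap1 (-2.42 ± 0.17), Ryr3 (-2.33 ± 0.50) and Coro2a (-2.29 ± 0.28). It was higher for Tcf7 (0.41 ± 0.09), for Lmna, the lamin A gene (3.18 ± 0.40), for Adamtsl2 (3.43 ± 0.75) and for Notch3 (2.96 ± 0.63). Of the fixed lists, immature single positive genes had a higher effect in naive cells, 5 of 11 and also 5 adjusted over the list alone, with Nr4a1 at 1.83 ± 0.26 (list adjusted p = 1.8e-06, and adjusted p = 0.00135 with an estimated correlation). Proliferation genes had a lower one, 6 of 24 and 8 adjusted over the list alone, with Mcm6 at -0.57 ± 0.12 (list adjusted p = 0.00027, but adjusted p = 0.282 with an estimated correlation). Inhibitory receptor and exhaustion genes had a higher effect in naive cells, 2 of 11 and 5 adjusted over the list alone. So did genes of CD4 T cells, 2 of 7 and 3 adjusted over the list alone. The list adjusted p values were 0.00025 and 0.00359, and adjusted p = 0.00732 and 0.0167 with an estimated correlation. These lists share members, so they are not separate results. Ikzf2 (2.31 ± 0.32) was called in both, and Nr4a1 stands in the inhibitory receptor and the immature single positive list. Of the CD4 T cell genes Zbtb7b (adjusted p = 0.566) and Foxp3 (adjusted p = 0.795) did not pass the edgeR test, and Cd4 was not tested. Without WT naive replicate 3 Adamtsl2 was at 4.94 and Notch3 at 5.11. Eomes lost its call without WT thymus replicate 2 (adjusted p = 0.125) and with only the compared libraries in the fit (adjusted p = 0.0657).

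From naive to memory cells the KO effect differed for 184 genes (69 higher in the memory effect, 115 lower). It was lower for Tbx21 (-1.85 ± 0.35), Cd44 (-1.62 ± 0.37), Cxcr3 (-1.33 ± 0.37), Pak6 (-3.38 ± 0.59) and Kcnj8 (-3.27 ± 0.65). It was higher for Gstm1 (2.54 ± 0.63), Dapk1 (2.21 ± 0.35) and Id2, an inhibitor of DNA binding (2.14 ± 0.24). Effector genes had a lower effect in memory cells, 2 of 11 and 3 adjusted over the list alone, with S100a6 at -2.53 ± 0.51 (list adjusted p = 2.1e-05, and adjusted p = 0.0404 with an estimated correlation). The effect in memory cells was also lower for inhibitory receptor and exhaustion genes (1 of 11, 5 adjusted over the list alone). The same held for genes of CD4 T cells (2 of 7, 3) and chemokine and cytokine receptor genes (2 of 22, 5). The list adjusted p values were 0.00018, 0.00034 and 0.00018, and adjusted p = 0.00471, 0.00471 and 0.00922 with an estimated correlation. Ikzf2 and Ctla4 stand in both the inhibitory receptor and the CD4 T cell list, so these are not separate results. Cd44 and Gstm1 lost their calls with only the compared libraries in the fit (adjusted p = 0.191 and 0.141). Gstm1 also lost it without KO memory replicate 3 or 4, KO naive replicate 2 or 3, WT memory replicate 2, 3 or 4, or WT naive replicate 2 or 3 (adjusted p = 0.0518 to 0.0918), and stood at 4.85 without WT memory replicate 1. Pak6 was at -5.54 without WT naive replicate 3. Cxcr3, at an adjusted p of 0.0496, lost its call when not robust (adjusted p = 0.0618), with the sex covariate (adjusted p = 0.0502) and without most single libraries (highest adjusted p = 0.170).

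Het libraries differed little from WT libraries in named genes. Lef1 was at 680 ± 43.9 CPM in Het and 745 ± 84.4 in WT memory libraries (log2 fold change -0.13 ± 0.07, adjusted p = 0.987, n = 4 each). Ezh2 was at 265 ± 30.6 in Het and 228 ± 22.3 CPM in WT thymus libraries (adjusted p = 0.821), and Cd44 at 1.70 ± 0.49 and 2.78 ± 1.12 CPM in naive libraries (adjusted p = 1). Atp8a2, a phospholipid transporter gene, was the 1 gene called, higher in Het memory libraries at 5.18 ± 0.89 against 2.87 ± 0.26 CPM (0.86 ± 0.16, adjusted p = 0.0486). It lost the call in DESeq2 (adjusted p = 0.0637), when not robust (adjusted p = 0.0545), with the block (adjusted p = 0.0505), with only the compared libraries in the fit (adjusted p = 0.934) and without any 1 of the 8 libraries except Het replicate 2 (adjusted p = 0.0728 to 0.233). edgeR called 0 genes in thymus and 0 in naive cells, with 636 and 275 genes at an unadjusted p under 0.05 and 527 in memory cells, and DESeq2 called 0, 0 and 1, the last being another gene than Atp8a2.

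The comparisons with Het libraries used the same 4 KO libraries of each subset as those with WT libraries, so the 2 sets of results are not independent. Lef1 fell by 0.56 ± 0.07 in thymus, 0.70 ± 0.07 in naive and 0.49 ± 0.07 in memory cells, and Eomes rose by 2.16 ± 0.19, 1.42 ± 0.16 and 1.08 ± 0.16 (n = 4 each). Within the same limits the highest fold changes were those of S100a6 (3.92 ± 0.40), Lgals3 (3.40 ± 0.46) and Lonrf3 (2.96 ± 0.37) in thymus and Dapk2 (4.78 ± 0.54), Gas7 (4.69 ± 0.73) and Zbtb16 (4.57 ± 0.51) in naive cells. In memory cells they were those of the plakoglobin gene Jup (5.04 ± 0.27), Pcdh7 (4.77 ± 0.53) and Glis3 (4.47 ± 0.53). The lowest were Izumo1r (-1.68 ± 0.23), Tuba3a (-1.48 ± 0.23) and Tmie (-1.25 ± 0.20) in thymus, Slc35g1 (-2.52 ± 0.23), Pcsk1 (-2.22 ± 0.32) and Igfbp4 (-2.21 ± 0.22) in naive and Plce1 (-4.95 ± 0.32), Dlg5 (-2.80 ± 0.38) and Tuba3a (-2.60 ± 0.31) in memory cells. Single libraries moved some of these: Gas7 was at 3.67 without KO naive replicate 3, Jup at 5.64 without Het memory replicate 4 and Pcdh7 at 5.36 without Het memory replicate 3. The test called 1971 genes in thymus (1221 higher, 750 lower), 1745 in naive (1076 and 669) and 2082 in memory cells (1198 and 884).

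The subsets themselves differed in the genes that define them. In WT libraries Cd44 was at 28.4 ± 3.47 CPM in memory and 2.78 ± 1.12 in naive cells (log2 fold change 3.30 ± 0.28), and Il2rb at 24.3 ± 3.16 and 5.92 ± 1.12 CPM. Tbx21 rose by 3.34 ± 0.27 and Lef1 fell by 0.74 ± 0.07. Within the same limits Gas7 (5.32 ± 0.61) and Dapk2 (5.14 ± 0.53) were among the highest, and the lowest were the gut homing receptor gene Ccr9 (-4.23 ± 0.24), Gria3 (-4.21 ± 0.30) and Itgae, the integrin CD103 (-3.30 ± 0.17). Without WT naive replicate 3 Gas7 was at 6.38 and Dapk2 at 6.28, and without WT memory replicate 1 Gria3 was at -4.98. Of 20 memory genes 15 rose (16 higher and 1 lower adjusted over the list alone). Of 15 glycolysis genes 10 rose, also adjusted over the list alone, with Pfkp at 0.88 ± 0.09. Of 14 cholesterol synthesis genes 7 fell (10 adjusted over the list alone). In this order the list adjusted p values were 1.2e-25, 2.7e-06 and 2.2e-05, and adjusted p = 0.00105, 0.0103 and 0.0629 with an estimated correlation. The test called 791 genes higher and 760 lower, and in KO libraries 895 higher and 887 lower. In KO libraries Itga4 fell by 1.43 ± 0.16, Lef1 by 0.65 ± 0.07, Ccr7 by 0.67 ± 0.09 and Dot1l by 0.28 ± 0.08, and Il2rb rose by 1.26 ± 0.17. Within the limits Ccr2 (3.18 ± 0.45), Fgl2 (3.03 ± 0.37) and Sulf2 (2.99 ± 0.51) had the highest and Tcf7l2 (-4.80 ± 0.37), Itgae (-4.60 ± 0.19) and Ccr9 (-4.21 ± 0.27) the lowest fold changes. Without KO naive replicate 3 Ccr2 was at 4.55 and Sulf2 at 3.90.

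From thymus to naive WT cells, all 24 proliferation genes fell, also adjusted over the list alone, with Mcm2 at -1.66 ± 0.08 and Rrm1 at -1.80 ± 0.11 (list adjusted p = 1.1e-38, and adjusted p = 0.00015 with an estimated correlation). Of 13 mature single positive genes 9 rose, 11 adjusted over the list alone, among them S1pr1 (1.08 ± 0.09). For the list the adjusted p was 9.1e-07 and adjusted p = 0.00191 with an estimated correlation. Of 11 immature single positive genes 8 fell (8 lower and 1 higher adjusted over the list alone), with Sox4 at -2.93 ± 0.22 (list adjusted p = 2.6e-10, and adjusted p = 2.7e-05 with an estimated correlation). Ezh2 fell by 1.77 ± 0.12 and Dot1l by 0.44 ± 0.09, and Eomes rose by 2.62 ± 0.22. Within the limits the highest fold changes were those of Rhob (4.30 ± 0.49), Cd55 (3.98 ± 0.23) and Ppm1j (3.45 ± 0.50) and the lowest those of the histone gene Hist1h1b (-5.34 ± 0.57) and the kinesin genes Kif4 (-5.15 ± 0.56) and Kif11 (-5.12 ± 0.56). Without WT naive replicate 3 Hist1h1b was at -6.34 and Kif11 at -5.78, and without WT thymus replicate 2 Ppm1j was at 4.13. The test called 1575 genes higher and 1744 lower in naive cells.

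Whether KO libraries outside the memory gate carried memory transcripts was tested with a signature from WT libraries alone, 267 genes higher and 212 lower in memory than in naive cells. Its score, the mean log2 CPM of the higher genes minus that of the lower genes, was -0.12 ± 0.47 in naive KO and -1.04 ± 0.09 in naive Het libraries (SD, n = 4 each), a difference of 0.92 (two-sided exact permutation p = 0.0286, the smallest the 70 splits can give). In thymus it was -0.99 ± 0.08 in KO (n = 4) and -1.81 ± 0.03 in WT libraries (n = 3), a difference of 0.82 (exact permutation p = 0.0286, the smallest of 35 splits). In memory cells it was 2.11 ± 0.10 in KO and 2.21 ± 0.24 in Het libraries (n = 4 each), a difference of -0.10 (exact permutation p = 0.457). That value was not stable: it was -0.22 without Het replicate 1 (exact permutation p = 0.0286), -0.0172 without Het replicate 3, and 0.0227 and 0.0304 with the signature at adjusted p alone and over a log2 fold change of 2. Of the 267 higher signature genes 106 were called higher and 31 lower, and of the 212 lower ones 80 higher and 19 lower. The WT memory and naive libraries lay 3.45 apart. The permutation for naive cells takes no account of equally numbered KO and Het libraries, which deviated together (correlations 0.115 to 0.174). Without 1 library the highest exact permutation p of the naive shift was 0.0571. The naive shift came with the higher genes, of which 175 were called higher and 6 lower against Het. Of the 212 lower genes 28 were called lower and 63 higher, with a median log2 fold change of 0.30. The thymus shift against WT also came with the higher genes, of which 147 were called higher and 6 lower. Of the lower genes 23 were called lower and 48 higher there, with a median log2 fold change of 0.14.

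**Figure D4:**
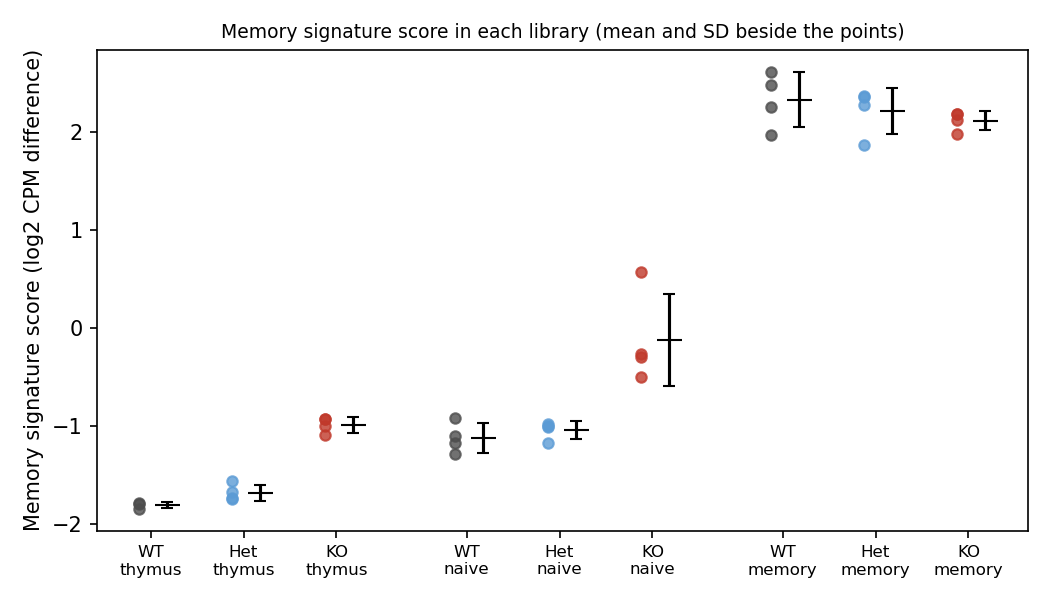
Memory signature score of each library by genotype and subset, with the mean of each group, on the log2 scale. Naive KO libraries averaged -0.12 against -1.04 in naive Het, thymus KO libraries -0.99 against -1.81 in thymus WT, and memory KO libraries 2.11 against 2.21 in memory Het libraries.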

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

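The tests of the GC and length trend apart from the centre, of the centring itself, of the split over 2-fold, of the B cell and myeloid genes, of the B cell genes without KO naive replicate 4, of the double positive genes and of the genes left after the comparison with WT memory libraries were chosen only after the result was seen.

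The effect of the KO differed between subsets in the interaction test for 653 genes from thymus to naive cells and for 184 genes from naive to memory cells. In the first it was lower in naive cells for Ezh2 (-0.76), Eomes (-1.01), Racgap1 (-2.42), Ryr3 (-2.33) and Coro2a (-2.29), and higher for Tcf7 (0.41), Adamtsl2 (3.43), Lmna (3.18) and Notch3 (2.96). In the second it was lower in memory cells for Tbx21 (-1.85), Cd44 (-1.62), Cxcr3 (-1.33), Pak6 (-3.38) and Kcnj8 (-3.27), and higher for Gstm1 (2.54), Dapk1 (2.21) and Id2 (2.14). Of 35 splits of the libraries, the real one included, 4 gave at least as many genes as the first count (highest other 1262). For the second count 2 did (highest other 2030). The splits with more genes than the first count exchanged the KO and WT labels of all naive libraries, and the one with 2030 those of all but 1 pair of naive libraries. This turns the naive effect around, so that the effects of both subsets add up. Since such splits keep the KO effect in the data, they cannot decide on chance for either count.

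A single library stood apart from the other 3 of its group by Dixon's rule in 10 of 136 sets of 4 values. The sets were levels of named genes, total counts and memory signature scores, each within 1 group. For normally distributed values the rule flags about 1 in 20, and levels from few counts need not follow that. In KO thymus replicate 3 S100a6 was at 37.0 CPM against 27.3 to 28.3 in the others. In KO naive replicate 3 Cd44 was at 17.95 CPM against 5.49 to 6.30 and Bhlhe40 at 26.4 against 10.95 to 12.84. In KO naive replicate 1 Pcsk1 was at 1.94 CPM against 0.986 to 1.08, and in WT naive replicate 1 Glis3 had 0 counts against 0.568 to 0.639 CPM. In WT memory replicate 4 Cxcr3 was at 9.59 CPM against 7.76 to 7.92 and Cdc42bpa at 1.17 against 0.219 to 0.311. In WT memory replicate 1 Kalrn was at 1.24 CPM against 0.219 to 0.358, Gstm1 at 2.56 against 0.0923 to 0.219 and Igfbp4 at 12.4 against 8.68 to 9.11.

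Over all splits, with the libraries taken as independent, chance was excluded for the genes changed between KO and WT libraries. There the real split alone, 1 of 35, reached its count: 1919 against 848 at most in thymus, 1879 against 89 in naive and 2283 against 4 in memory cells. The same held for KO against Het (1971 against 115, 1745 against 27 and 2082 against 11), for memory against naive in WT (1551 against 12) and KO (1782 against 401), and for naive against thymus (3319 against 2246). The 848 and the 2246 came from splits that kept all 3 WT thymus libraries together with 1 other. Equally numbered libraries deviated together in KO against WT naive, KO against Het naive and memory against naive WT libraries. There the 7 other splits that part all 4 pairs, as the real one does, called 0 genes at most, and the 27 that part fewer pairs 89, 27 and 12 at most. These 8 splits are too few for a share under 0.05, so with the pairs kept chance was not excluded for these counts. Equally numbered memory and naive KO libraries also deviated together on average (mean correlation 0.137, lowest 0.0763). So did KO and WT memory libraries (mean 0.109, lowest 0.0205) and KO and Het memory libraries (mean 0.0801, lowest 0.0682). Splits of these comparisons were not sorted by the pairs they part. Chance was excluded there only with the libraries taken as independent. In naive cells 9 lists were called, against 8 at most in the other 34 splits and 6 at most in those that part all 4 pairs, but only 7 without WT naive replicate 1, so no statement on chance is made for that count. For the number of lists called it was not excluded in thymus (8, with 5 splits as large and 9 at most) or memory cells (7, with 13 as large and 11 at most). For Het against WT memory libraries it was not excluded either (1 gene, 3 splits as large, highest other 6). In thymus and naive cells edgeR and DESeq2 called 0 genes (636 and 275 at an unadjusted p under 0.05 in edgeR), a count that all 35 splits reach, so the splits (highest other 24 and 1) say nothing there.

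More genes were higher than lower in KO than in WT libraries in all 3 subsets with TMM scaling. Over 2-fold they were 496 against 47 in thymus, 585 against 64 in naive and 701 against 116 in memory cells. The lowest share of higher genes there was 78.5% under RLE scaling or centring on the mean log level. After correction for GC content and length it was 79.5%. This argues against GC and length bias, and against scaling shifts of the size tried, as the source of that part. The centring moved the median gene by only -0.10 to -0.12 on the log2 scale. It could hardly turn a split of changes over 2-fold, so larger scaling errors were not tested. Over all calls both stay open: centring on the mean log level, which fixes the mean fold change at 0, gave 34.5% at the lowest, and the GC and length correction 30.7% as first run, when it also re-centred the libraries, and 53.8% with the TMM centre kept. RLE scaling gave 59.1%, above the 55% set in advance as excluding scaling, but that bound was too narrow, since RLE and TMM both centre on the typical gene. An effect of the genotype on many genes may account for the pattern and was not told apart from scaling and GC or length bias for changes under 2-fold. For changes over 2-fold it was not told apart from a limit of detection, since genes at a low level can hardly be seen to fall.

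The 1147 genes higher in naive KO than in naive WT libraries could come from memory cells of WT type inside the gate, although sorting CD44 negative cells would remove them. A mixture of both WT cell types lies between them. However, 63.0% of the genes (723) were also called higher in naive KO than in WT memory libraries. This argues against memory cells of WT type as the whole source. For the other 424 genes, 61.6% of them called higher in WT memory than in WT naive libraries, that source stays open. Memory cells of KO type inside the gate were not tested. In memory cells 815 of the 1147 genes were also higher in KO than in WT libraries, so WT memory libraries cannot stand for them. B cells, which a CD8 sort would remove, were argued against as the source of most of these genes: B cell genes were high in KO naive replicate 4 (H2-Aa at 73.2 CPM against 2.81 to 32.0 in WT naive libraries, and Ighm, the most abundant, at 250 against 181 to 235), but without it 984 of the 1147 genes were still called, while the 10 B cell genes then tested had a median log2 fold change of -1.01 (SE 0.30). With all libraries edgeR called 0% of 14 B cell and myeloid genes higher, though the median of the 12 B cell genes was 0.73 against 1.03 for the called genes, and myeloid cells, most of which the sort would also remove, stay open with 2 tested genes. An effect of the genotype within naive cells may also account for the pattern and was not told apart.

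Proliferation genes were higher in thymus KO than in thymus WT libraries, with a median log2 fold change of 0.84. One library alone was not the source, since the lowest median without 1 library was 0.72. Double positive thymocytes inside the gate stay open: the median of the 9 tested double positive genes differed from that of the proliferation genes by -0.96 (SE 0.26), but these genes went both ways, and Rag1 was called higher (1.21 ± 0.40). More dividing cells among the single positive cells, or an effect of the genotype within cells, may account for it, and neither was tested.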

How the results depend on the processing

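Of the alternatives, the tests with a sex covariate and with centring on the mean log level were chosen only after the result was seen. The counts of genes changed between KO and WT or Het libraries, between subsets and in the interaction tests stayed within 1.5 times the reported count under every alternative run for them, and so did the overlaps under RLE scaling, the stricter filter, DESeq2 and the block, while centring turned the split of higher against lower genes. Without 1 library KO against WT called 1409 to 1792 genes in thymus, 1573 to 1752 in naive and 1971 to 2081 in memory cells, and the interaction tests 461 to 628 and 148 to 178. With the replicate number as a block, a pairing the labels do not give, KO against WT called 1906, 2025 and 2435 genes. In thymus the data do not bear that pairing out. By Xist and Y-linked transcripts only 1 of 3 equally numbered KO and WT thymus pairs matched in sex. Their deviations did not go together (correlations -0.0856 to 0.0495). The count of lists called in KO against WT fell with an estimated correlation to 4 in thymus, 2 in naive and 0 in memory cells, since that test widens the spread of each list by its own correlation. Het against WT memory libraries called 1 gene, but 3 with no filter on low counts, 0 when not robust, 2 each with RLE scaling, the sex covariate and mean log centring, and 0 to 1 without 1 library (0 without Het replicate 1 or any 1 WT replicate). The 1 gene was not Atp8a2 in DESeq2, with the block, with only the compared libraries or without Het replicate 3 or 4. Het against WT naive libraries called 1 gene with no filter, and thymus libraries 0 to 2 without 1 library (2 without Het replicate 2). The cause was not tested. The signature shift with the block was 0.92 in naive KO (exact p = 0.125) and 0.86 in thymus KO (exact p = 0.25), the smallest p that 4 and 3 pairs can give, which says nothing about stability. Without 1 library it was 0.69 to 1.06 in naive KO, with an exact p of 0.0571 without Het naive replicate 1 (0.87), and 0.78 to 0.88 in thymus KO, where the smaller designs cannot give an exact p under 0.0667 or 0.1. In memory KO it was 0.0227 with the signature at adjusted p alone, 0.0304 over a log2 fold change of 2 and -0.22 to -0.0172 without 1 library, the ends without Het memory replicates 1 (exact permutation p = 0.0286) and 3. The cause was not tested. Of 140 calls of named genes 13 were lost in some alternative, 6 of the other named results gained a call, and 0 reversed. Depth limits genes with few counts, whose fall can hardly be seen.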

Other observations

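The hypotheses on basal level and on the genes near Dot1l were set before their results were seen, while the tests of the spread of the basal levels were chosen only after the result was seen, and Slc35g1 and Plce1 were set side by side after their values were seen.

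Genes of the PRC2 complex changed one by one in KO libraries. Phf19, an accessory subunit, rose by 1.66 ± 0.21 in thymus, 2.25 ± 0.25 in naive and 1.97 ± 0.21 in memory cells, while Jarid2, another, fell by 0.49 ± 0.07 in thymus and 0.49 ± 0.07 in memory cells. Of the 12 subunit genes 2 rose and 3 fell in thymus, 1 and 1 in naive and 2 and 2 in memory cells, and the list was not called (adjusted p = 0.952, 0.759 and 0.904). Of 15 genes of DOT1L and its partners 3 rose and 2 fell in thymus, 2 and 4 in naive and 1 and 3 in memory cells (list adjusted p = 0.952, 0.957 and 0.579). The elongation factor gene Ell2 rose by 1.84 ± 0.37 in naive and 2.01 ± 0.33 in memory cells. Of 22 chemokine and cytokine receptor genes 7 rose and 4 fell in thymus, 6 and 4 in naive and 4 and 6 in memory cells (list adjusted p = 0.919, 0.87 and 0.0589). Cxcr4 rose (0.81 ± 0.15, 0.91 ± 0.14 and 1.01 ± 0.13) and Il6st, a shared cytokine receptor chain, fell (-0.83 ± 0.11, -1.04 ± 0.10 and -1.32 ± 0.11) in thymus, naive and memory cells. Slc35g1 (-0.88, -2.85 and -2.17) and Plce1 (-3.41, -3.99 and -4.71) were called lower in thymus, naive and memory cells. Both lie on chromosome 19, from 38395980 to 38405610 and from 38481109 to 38785030.

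From naive to memory cells in KO libraries 12 of 24 proliferation genes rose, with Mcm2 at 0.83 ± 0.07 (list adjusted p = 6.9e-10, and adjusted p = 0.0406 with an estimated correlation). Of 17 activation and immediate early genes 6 fell, with Egr3 at -2.14 ± 0.23 and Egr1 at -1.23 ± 0.22 (list adjusted p = 0.00035, but adjusted p = 0.125 with an estimated correlation). From thymus to naive cells in WT libraries 12 of 21 interferon stimulated genes fell, with Rsad2 at -2.77 ± 0.33 and Mx1 at -1.63 ± 0.24 (list adjusted p = 0.00023, but adjusted p = 0.16 with an estimated correlation). There 7 of 11 inhibitory receptor and exhaustion genes fell, with Ikzf2 at -3.17 ± 0.24 and Tox at -1.25 ± 0.09 (list adjusted p = 3.5e-08, and adjusted p = 0.00011 with an estimated correlation). Of the PRC2 genes 7 fell and 2 rose, with Phf19 at -2.35 ± 0.26 (list adjusted p = 0.00703, and adjusted p = 0.0402 with an estimated correlation). Of 12 B cell genes 6 were higher in naive cells (list adjusted p = 0.00703, but adjusted p = 0.446 with an estimated correlation).

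A hypothesis was that genes of low basal level rose and genes of high basal level fell in KO libraries, read in Het libraries, which enter neither side of the comparison. The median log2 CPM in Het libraries was 3.46 for higher and 6.23 for lower genes in thymus, 2.40 and 6.25 in naive and 2.12 and 6.01 in memory cells, a smallest difference of 2.77. Genes that were not called lay at 3.53, 3.60 and 3.63. The lower genes lay above these in each subset, but the higher genes differed from them by -0.07 (SE 0.15) in thymus, against -1.21 (SE 0.16) in naive and -1.51 (SE 0.10) in memory cells, so the part on low levels had no support in thymus. Genes at a low level can hardly be seen to fall, and high KO counts can bring genes low in the other libraries into the test, either of which may account for the pattern, so the hypothesis stays open.

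Another hypothesis was that variants linked to the floxed allele changed genes around Dot1l. Within 10 megabases of it 16 of 149 tested genes were called in thymus, 16 in naive and 23 in memory cells. These shares of 10.7%, 10.7% and 15.4% were lower than the 18.8%, 18.4% and 22.3% elsewhere, with a highest ratio of 0.69, which argues against an excess of calls there.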
